A study of Mus musculus with 16 samples.

How the data were processed

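Whole dorsal skin of female C57/B6 mice was measured on Affymetrix mouse arrays, with 16 arrays from 9 mice. The sample titles write C57/B7 and the other label fields C57/B6, and the latter was used. Mice 1 to 9 gave a day-0 array each, and 7 of them (mice 2, 3, 4, 6, 7, 8 and 9) also a day-5 array. Per the labels, RNA was extracted with a column kit from flash-frozen tissue, and cDNA was amplified (NuGEN Ovation) and labelled with biotin. The deposited values are log2 expression values per probe set, made by the authors with GCRMA (background correction, normalization across arrays and summary of each probe set), per the submitters' processing notes. The version of GCRMA, and whether all arrays were normalized together, are not given in the sources used here. The description of the tofacitinib array of mouse 7 names ruxolitinib while its other fields name tofacitinib. It was grouped by those other fields, which limits every tofacitinib value.

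Groups were taken from the labels only: day 0 (n = 9), vehicle at day 5 (n = 2), ruxolitinib at day 5 (n = 2) and tofacitinib at day 5 (n = 3). The groups, comparisons, tests, lists, named-gene rule and alternatives were fixed before the data were examined, except for 3 alternatives chosen after seeing the data and the tests named in the closing section as chosen after the results were seen. Of the probe sets, 35890 were in the platform's gene table, 34958 with 1 gene symbol and 932 with several, and 9211 were not listed. Symbols were checked by gene ID against the mouse reference table (34754 probe sets matched, 0 symbols changed), which was used for names only. Probe sets without exactly 1 symbol were left out of the gene tests. A probe set was kept when its log2 value exceeded 4 in at least 2 arrays (20992 probe sets), and the kept probe set with the highest mean stood for its gene. This left 12087 of 18194 genes, of which 5297 had more than 1 kept probe set and 11349 had a median above 4. Array medians lay between 3.75 and 3.94, against a median of 1.70 and a highest value of 2.43 in 27 control probe sets without a target.

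Genes were tested with limma 3.58.1 in R 4.3.3. The fit had a mean for each of the 4 groups on all 16 arrays, with the mouse as a random block (duplicateCorrelation, consensus correlation 0.0982) and empirical Bayes moderation (12 residual and 2.86 prior degrees of freedom). The p values were adjusted by Benjamini-Hochberg within each of the 7 comparisons, and genes passed at an adjusted p under 0.05. The comparisons were each day-5 group against day 0, each inhibitor and the mean of both against vehicle at day 5, and tofacitinib against ruxolitinib. A value that missed the threshold was not read as equality. Errors of log2 differences are standard errors and intervals are 95% intervals from the same fit. Folds are 2 to the power of the log2 difference. Where every array of a group lay at or under 2.43, the highest control value, the fold was given as a lower bound against that value. This bound uses a group mean and leaves out sampling error. For Cd3d it (8.18) exceeded the fitted fold (8.11), so the fitted log2 change is given instead. Where only some arrays of a group lay at or under 2.43, the size of the log2 difference is uncertain. The day-0 and day-5 samples are paired per the labels, which place both biopsies on the same mouse. As a check, deviations of an animal's 2 arrays from their group means were correlated. The correlation exceeded 0.1 in 2 of 7 pairs (range -0.183 to 0.178), and 1 day-5 array correlated best with its own day-0 array.

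In all, 32 gene lists were fixed, and 29 with at least 3 tested members were tested with cameraPR on the moderated t, with a preset inter-gene correlation of 0.01 and again with a correlation estimated per list. Adjustment was over the 29 lists of a comparison. Neutrophil, erythrocyte and B cell lists had too few tested members. Other lists were tested only in part, such as 5 of 26 hair shaft, 6 of 13 inner root sheath and 9 of 23 T and NK cell members. Counts of members passing are given with adjustment over all genes and over the list alone. For 12 lists over all comparisons the median, the mean and the test differed in sign, and 0 of these were called.

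The named genes were fixed by rule. They were the 10 largest rises and 10 largest falls of each comparison among genes that passed and whose arrays did not overlap, leaving out symbols of predicted genes. Where fewer than 5 passed in a direction, they were the 5 with the smallest p. From each list described, the 4 members with the smallest p were added, and always the Janus kinases and Cish, Socs1, Socs2 and Socs3 where tested. The text prints a part of these. Of the 160 printed results 42 had more than 1 kept probe set, and in 21 of these the probe sets lay more than 1 log2 unit apart.

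Scripts were tested on simulated data in which 200 genes were changed by known folds, 50 per fold. At 4-fold, 92% were recovered for tofacitinib against day 0, 90% for ruxolitinib against vehicle, 90% for tofacitinib against vehicle and 84% for both inhibitors against vehicle. At 2-fold these were 72%, 36%, 40% and 64%. False calls made up 6.59%, 7.14%, 6.80% and 3.25%, and the moved list alone was called each time. The simulated genes varied independently of each other, so this does not measure false list calls where the genes of a list vary together.

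Within-mouse changes were day 5 minus the animal's own day 0, averaged per arm and correlated across genes without a p value. For differences from vehicle, which share arrays, 100 simulations without an effect gave the reference, with each gene drawn independently. The alternatives were the low-value filter, the mouse term, separate day-0 means, only the groups compared, trended robust moderation, quantile normalization, array weights, the choice of probe set, a skeletal muscle covariate, other thresholds and each array left out. Those added after seeing the data were a basal keratinocyte covariate, a covariate of the 3' minus 5' signal of actin and Gapdh control probe sets, and a fit without the day-0 arrays of mice 1, 3, 8 and 9.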

Results

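Whole dorsal skin of female C57/B6 mice, an inbred laboratory strain, was profiled on arrays before and after a short topical treatment. A first biopsy was taken at day 0, when the mice were 8.5 weeks old, and a second at day 5, after 4 days of daily application. The treatments were dimethyl sulfoxide (DMSO, the solvent used as vehicle), ruxolitinib and tofacitinib. Both drugs inhibit Janus kinases (JAKs), the enzymes that pass the signals of many cytokine receptors to STAT transcription factors. Both carry a pyrrolopyrimidine ring, joined to a pyrazole in ruxolitinib and to a piperidine in tofacitinib. The doses are not given in the sources used here. The 16 arrays comprised 9 taken at day 0 (mice 1 to 9), 2 of vehicle at day 5 (mice 2 and 3), 2 of ruxolitinib at day 5 (mice 4 and 6) and 3 of tofacitinib at day 5 (mice 7, 8 and 9). The values were log2 GCRMA values, and 12087 genes were tested. Array medians lay between 3.75 and 3.94, and the 27 control probe sets without a target had a median of 1.70 and reached at most 2.43. The number of arrays limited the precision. Correlations across probe sets, which are not independent replicates, ran from 0.978 to 0.996 between day-0 arrays and from 0.984 to 0.993 between day-5 arrays. Between the days they ran from 0.946 to 0.983, and the leading principal component held 65.5% of the variance. One free-text field of the tofacitinib array of mouse 7 names ruxolitinib, while its title, source and treatment field name tofacitinib, and it was analysed as tofacitinib.

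Vehicle-treated skin was compared with day 0 to see what changed without an inhibitor. Fosl1, a subunit of the AP-1 transcription factor (Entrez gene 14283), rose 39.1-fold, a log2 change of 5.29 ± 1.02 (SE, 2 against 9 arrays, adjusted p = 0.000786), but its other kept probe set rose by only 1.10. Mmp10, a matrix-degrading stromelysin (Entrez gene 17384), rose 32.5-fold (5.02 ± 0.50, adjusted p = 4.36e-06), and Krt16, a keratin of stressed epidermis, rose 15.7-fold (3.97 ± 0.52, adjusted p = 3.86e-05). T cell receptor complex genes went the other way. Cd3g fell by 3.80 ± 0.39 on the log2 scale (adjusted p = 6.15e-06) and Cd3d by 3.02 ± 0.43 (adjusted p = 8.47e-05). Cd3d lay at background in the vehicle arrays, so the size of its fall is uncertain. In all, 6178 of 12087 genes changed, 2685 higher and 3493 lower.

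Of the 32 cell cycle genes, 27 fell in vehicle skin and 5 did not pass (27 fell and 1 rose adjusted over the list alone). The mitotic checkpoint kinase Bub1b fell by 3.08 ± 0.34, the spindle protein Nusap1 by 3.83 ± 0.52 (its other probe set stood at -0.29) and the proliferation marker Mki67 by 1.90 ± 0.27 (list adjusted p = 7.53e-07, and adjusted p = 0.449 with an estimated correlation). Among 21 epidermal differentiation genes 16 fell and 5 did not pass (18 fell adjusted over the list alone), including Krt1, the suprabasal keratin, by 0.95 ± 0.13 and Lce1m, a cornified envelope protein, by 1.38 ± 0.17 (adjusted p = 1.01e-05, and adjusted p = 0.382 with an estimated correlation). Basal and outer root sheath keratinocyte markers fell in 11 of 12 cases, also adjusted over the list alone. Krt15 fell by 1.36 ± 0.15 (list adjusted p = 7.84e-05, and adjusted p = 0.332 with an estimated correlation). Of 17 activated keratinocyte genes 8 rose and 3 fell, with the same numbers adjusted over the list alone. The urokinase receptor gene Plaur rose by 1.05 ± 0.18 (list adjusted p = 0.0361, and adjusted p = 0.465 with an estimated correlation). The activated keratinocyte call was lost without vehicle mouse 2 (adjusted p = 0.0566), with separate day-0 means (0.0518), with a filter at 6 (0.0562) and without a filter (0.185).

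Of the 15 Wnt ligands and target genes, 11 fell and 4 did not pass, also adjusted over the list alone. Fzd10, a Wnt receptor, fell by 3.52 ± 0.31 and Rnf43, a Wnt feedback inhibitor, by 2.75 ± 0.26 (adjusted p = 0.000242, and adjusted p = 0.0471 with an estimated correlation). Of 13 BMP pathway genes 9 fell and 2 rose, also adjusted over the list alone. Bmp4 fell by 2.24 ± 0.25 and Fgf18, a growth factor of resting hair follicles that had been placed on this list, by 2.93 ± 0.32 (list adjusted p = 0.0215, and adjusted p = 0.465 with an estimated correlation). The hedgehog list had 6 of 10 members lower, also adjusted over the list alone (adjusted p = 0.0150, and adjusted p = 0.382 with an estimated correlation), while its ligand Shh did not pass (-0.37 ± 0.61, adjusted p = 0.629). Rspo3, a Wnt amplifier made by dermal papilla cells, fell by 4.51 ± 0.37 (adjusted p = 1.10e-06).

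T cell and interferon-stimulated genes fell with vehicle as well. Of 9 T and NK cell markers 8 fell (adjusted p = 0.000506, and adjusted p = 0.382 with an estimated correlation), as did all 4 tested regulatory T cell markers (adjusted p = 0.0168, and adjusted p = 0.382 with an estimated correlation), with the same counts adjusted over each list alone. The regulatory T cell call was lost without a filter (adjusted p = 0.0809). Of 26 interferon-stimulated genes 12 fell and 14 did not pass, also adjusted over the list alone (adjusted p = 0.00676, and adjusted p = 0.476 with an estimated correlation). Examples were the immunoproteasome subunits Psmb9 (-3.56 ± 0.38) and Psmb8 (-2.89 ± 0.30, and -0.24 for its other probe set), the peptide transporter Tap1 (-2.64 ± 0.27) and the interferon feedback protease Usp18 (-3.17 ± 0.36). Cish, a STAT5 feedback inhibitor, fell by 2.07 ± 0.45 (adjusted p = 0.00190), and Socs3, a STAT3 feedback inhibitor, did not pass (-0.43 ± 0.29, adjusted p = 0.235). As a list, the 14 JAK-STAT feedback and target genes did not pass (3 higher and 4 lower, also adjusted over the list alone, adjusted p = 0.938). Its median of -0.08 and mean of -0.01 lay below 0 while its test pointed up.

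Markers of other tissue layers moved with the same groups. Of 20 skeletal muscle genes 13 rose (15 adjusted over the list alone, median log2 change 0.73, adjusted p = 9.27e-05, and adjusted p = 0.465 with an estimated correlation). Outside that list the muscle genes Tnnt1, Actc1, Myl2 and Mybph rose by 5.69 ± 0.73, 5.33 ± 0.45, 5.30 ± 0.84 and 4.77 ± 0.43. Endothelial markers rose in 12 of 14 cases (13 adjusted over the list alone, adjusted p = 1.39e-05, and adjusted p = 0.382 with an estimated correlation), with Vwf up by 2.46 ± 0.39 and Flt1 by 3.22 ± 0.63 (2.18 in the lowest of its probe sets). Among 14 fibroblast markers 10 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00126, and adjusted p = 0.449 with an estimated correlation), with Lum up by 2.40 ± 0.47 and Pi16 by 2.99 ± 0.65 (1.70 in its other probe set). Of 7 Schwann cell markers 6 rose (7 adjusted over the list alone, adjusted p = 0.00676, and adjusted p = 0.465 with an estimated correlation). Of 13 adipocyte markers 2 rose (0 adjusted over the list alone in limma, adjusted p = 0.0336, and adjusted p = 0.645 with an estimated correlation). The adipocyte call was lost without vehicle mouse 3 (adjusted p = 0.0582), without a filter (0.0544), with the 3' minus 5' covariate of RNA quality (0.197) and without the day-0 arrays of mice 1, 3, 8 and 9 (0.0919), both alternatives chosen after seeing the data. With the muscle covariate adipocytes stood at -1.27 (adjusted p = 0.0278) and Schwann cells at 0.13 (0.236). With the muscle list mean of each array as a covariate 2593 genes changed, Cish (adjusted p = 0.0814), Flt1 (adjusted p = 0.056) and Pi16 (adjusted p = 0.114) no longer passed and Socs3 stood at 0.04. The muscle mean separated the days completely, so it takes up part of their difference by construction. With the basal keratinocyte mean, a covariate chosen after seeing the data whose arrays separate the days completely, 5 changed and Itgb4, a basal integrin that had fallen by 2.57 ± 0.33, stood at 0.21. With the mouse as a fixed block 3701 genes changed, without vehicle mouse 2 there were 3470, without vehicle mouse 3 there were 4001, and at an absolute log2 change of at least 1 there were 3071.

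**Figure D1:**
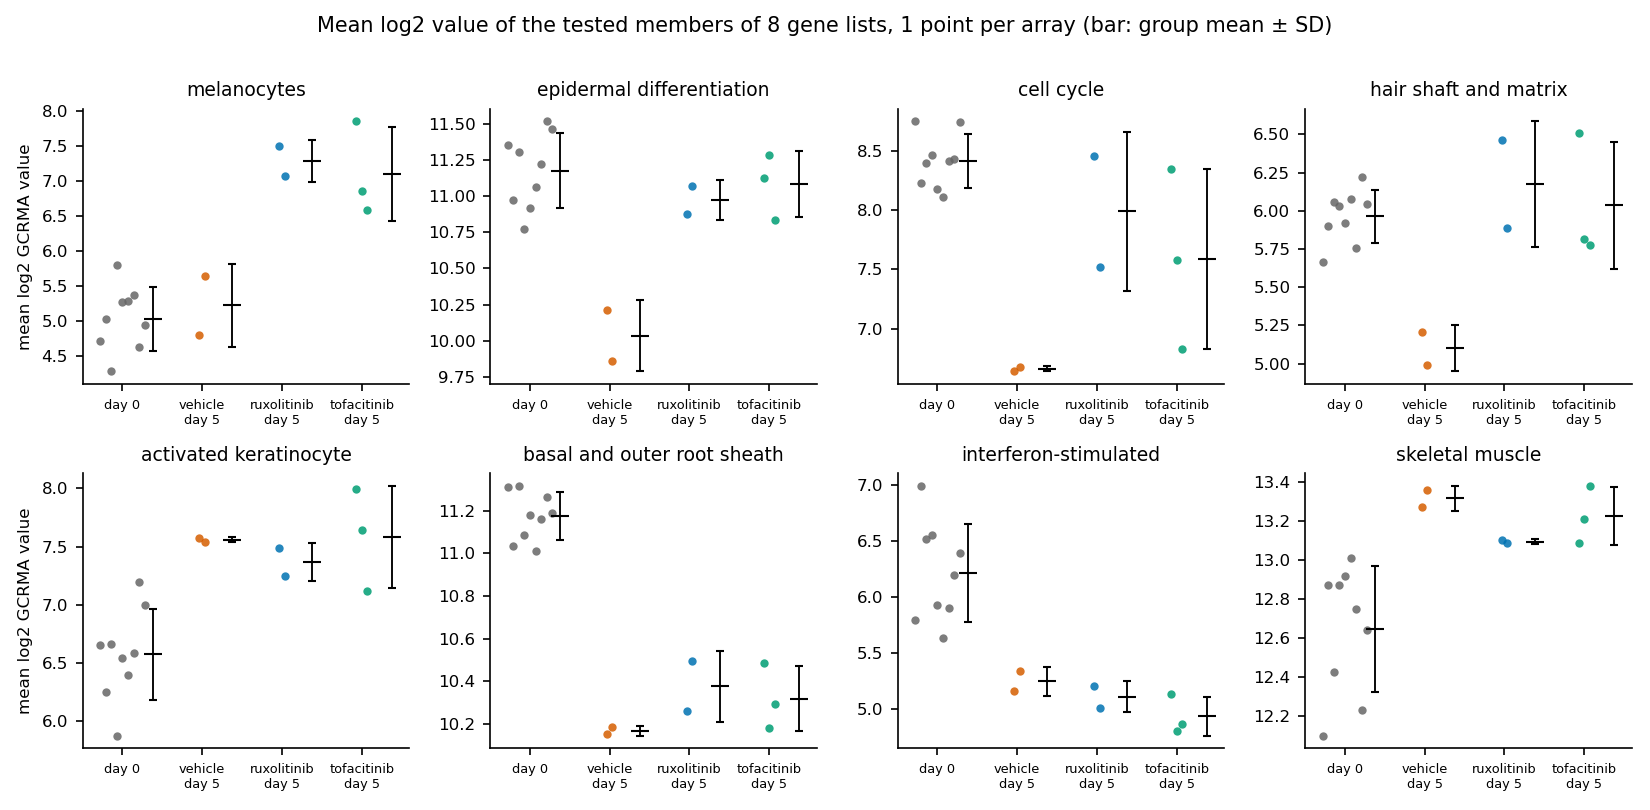
Mean log2 GCRMA value of the tested members of 8 gene lists (vertical axes, each with its own range) in the 4 groups, with 1 point per array and bars for the group mean ± SD. The melanocyte list mean was at least 6.59 in the 5 inhibitor arrays and at most 5.80 in the other 11, and the basal keratinocyte list separated day 0 from day 5.

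Skin treated with either inhibitor was compared with day 0 in the same way. Ruxolitinib skin had 4104 changed genes, 1512 higher and 2592 lower, and tofacitinib skin 6055, 2742 higher and 3313 lower. Pigment cell genes rose with both. Tyrp1, a melanin synthesis enzyme (Entrez gene 22178), rose 13.3-fold with ruxolitinib (3.74 ± 0.39, adjusted p = 1.39e-05) and 10.8-fold with tofacitinib (3.43 ± 0.33, adjusted p = 3.29e-06), and Pmel, which forms the melanosome matrix, 6.62-fold and 6.45-fold. The lowest of the 3 Tyrp1 probe sets rose by 1.75 with either drug. Tyr, the enzyme that starts melanin synthesis, lay at background at day 0 and rose at least 3.91-fold and at least 3.13-fold. Of 8 melanocyte genes 6 rose in either drug (6 rose with each, and 1 fell with tofacitinib, adjusted over the list alone). The list's adjusted p was 7.19e-05 for ruxolitinib (adjusted p = 0.232 with an estimated correlation) and 0.000333 for tofacitinib (adjusted p = 0.293 with an estimated correlation).

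Several of the largest changes were common to both drugs. Procr, the endothelial protein C receptor, rose by 4.71 ± 0.31 with ruxolitinib and 4.90 ± 0.27 with tofacitinib, and Fosl1 rose by 5.98 ± 1.02 and 4.95 ± 0.86 (1.40 and 1.32 in its other probe set). Hamp2, a hepcidin gene, fell 109-fold and 114-fold, Sectm1a, a ligand of the T cell molecule CD7, by 5.30 ± 0.31 and 5.07 ± 0.26, and Ifitm6, an interferon-induced membrane protein gene, by 4.99 ± 0.78 and 4.98 ± 0.66. Cxcl13, a B cell chemoattractant, rose by 4.29 ± 0.65 with ruxolitinib (1.93 in its other probe set), and Tmprss11a, a transmembrane serine protease gene, by 5.56 ± 0.41 with tofacitinib. The vehicle skin shared part of this. Hamp2 fell by 4.87 ± 0.48 and Sectm1a by 4.66 ± 0.31 there, and of the 6178 genes changed with vehicle 3240 passed in the same direction with ruxolitinib and 4883 with tofacitinib. These comparisons used the same 9 day-0 arrays, so part of that overlap may come from the shared controls.

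Socs3, Cish and part of the interferon-stimulated genes fell with both drugs, while Cish and 12 of the interferon genes had also fallen with vehicle. Socs3 fell by 1.85 ± 0.29 (adjusted p = 0.000315) and 1.81 ± 0.25 (adjusted p = 5.93e-05), and Cish by 2.33 ± 0.45 and 1.75 ± 0.38. Of 26 interferon-stimulated genes 13 fell and 1 rose with ruxolitinib (13 fell and 2 rose adjusted over the list alone, adjusted p = 0.000632, and adjusted p = 0.479 with an estimated correlation). With tofacitinib 18 fell and 1 rose (19 fell and 1 rose adjusted over the list alone, adjusted p = 7.89e-05, and adjusted p = 0.359 with an estimated correlation). Usp18 fell by 4.18 ± 0.36 and 4.23 ± 0.31 and Psmb9 by 3.69 ± 0.38 and 3.76 ± 0.32. The T and NK cell list fell (8 of 9 genes with each, adjusted p = 3.64e-05 and 5.18e-05, and adjusted p = 0.195 and adjusted p = 0.212 with an estimated correlation), with 8 and 9 lower adjusted over the list alone, and Cd3g fell by 4.30 ± 0.39 and 3.55 ± 0.33. The JAK-STAT feedback and target list had 3 genes higher and 6 lower with each drug, also adjusted over the list alone, and did not pass (adjusted p = 0.356 and 0.653). Of the 17 JAK-STAT pathway components 9 fell with ruxolitinib (10 adjusted over the list alone, adjusted p = 0.0186, and adjusted p = 0.165 with an estimated correlation). This call was lost without ruxolitinib mouse 4 (adjusted p = 0.0699) and with the mean of probe sets (0.124). With tofacitinib 10 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.0431, adjusted p = 0.196 with an estimated correlation and 0.0573 with the mouse as a fixed block). This call was also lost without tofacitinib mouse 7 (adjusted p = 0.0756) or 8 (0.0512), with the mean of probe sets (0.215) and with a filter at 6 (0.0534). Stat5a fell by 1.22 ± 0.14 with tofacitinib. The component list was lower with vehicle too. Its mean was 9.04 at day 0, 8.62 with vehicle, 8.53 with ruxolitinib and 8.59 with tofacitinib. Its member Tyk2 fell by 1.73 ± 0.21 with vehicle, 1.35 ± 0.21 with ruxolitinib and 1.47 ± 0.18 with tofacitinib. The fall of this list from day 0 is therefore not particular to the inhibitors.

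Cell cycle genes fell in 4 of 32 cases and rose in 1 with ruxolitinib (2 and 1 adjusted over the list alone, list adjusted p = 0.248). They fell in 22 cases and rose in 1 with tofacitinib (23 and 1 adjusted over the list alone, adjusted p = 0.00135, and adjusted p = 0.494 with an estimated correlation), and with the muscle covariate the tofacitinib call was lost (adjusted p = 0.186). Epidermal differentiation genes did not pass as a list with either drug (4 lower and 1 higher of 21, adjusted p = 0.248, and 7 lower and 2 higher, adjusted p = 0.386). Adjusted over the list alone these were 4 lower and 1 higher, and 7 lower and 1 higher. Activated keratinocyte genes rose with both (7 rose and 2 fell of 17, adjusted p = 0.0255, and 9 rose and 2 fell, adjusted p = 0.0228, with adjusted p = 0.479 and adjusted p = 0.494 with an estimated correlation). Adjusted over the list alone 7 and 10 rose and 2 fell with each. For tofacitinib this call was lost with the mouse as a fixed block (adjusted p = 0.150), with separate day-0 means (0.207), without a filter (0.128) and without tofacitinib mouse 7 (0.0953). For ruxolitinib it was lost without ruxolitinib mouse 4 (0.0545), with only the groups compared (0.0615), with the mean of probe sets (0.0534) and without a filter (0.0939).

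Muscle markers rose with these groups too. Of 20 muscle genes 3 rose with ruxolitinib (0 adjusted over the list alone in limma, median 0.45, adjusted p = 0.00191, adjusted p = 0.542 with an estimated correlation 0.0874 with the mouse as a fixed block and 0.0858 with separate day-0 means), and 16 with tofacitinib (17 adjusted over the list alone, median 0.60, adjusted p = 8.50e-05, and adjusted p = 0.494 with an estimated correlation). Myl2 and Tnnt1 rose by 4.28 ± 0.84 and 4.18 ± 0.73 with ruxolitinib (adjusted p = 0.0637 and 0.0639 with the mouse as a fixed block), and by 5.35 ± 0.72 and 4.83 ± 0.62 with tofacitinib. Endothelial markers rose in 10 and 14 of 14 cases (12 and 14 adjusted over the list alone, adjusted p = 2.49e-05 and 1.96e-05, and adjusted p = 0.232 and adjusted p = 0.263 with an estimated correlation). Fibroblast markers rose in 11 of 14 cases and fell in 1 with ruxolitinib, also adjusted over the list alone, and rose in 12 with tofacitinib (13 rose and 1 fell adjusted over the list alone). Their list adjusted p was 2.31e-05 and 5.18e-05 (adjusted p = 0.232 and adjusted p = 0.293 with an estimated correlation). Adipocyte markers rose in 1 and 5 of 13 cases (0 in limma and 9 adjusted over the list alone, adjusted p = 0.00876 and 0.00609, and adjusted p = 0.542 and adjusted p = 0.494 with an estimated correlation). The ruxolitinib adipocyte call was lost with the mouse as a fixed block (adjusted p = 0.0622), with separate day-0 means and with the muscle covariate (0.774), where the tofacitinib median was -0.48 (adjusted p = 0.272). Schwann cell markers rose in 2 and 3 of 7 cases (3 and 3 adjusted over the list alone, adjusted p = 0.0122 and 0.0431, and adjusted p = 0.479 and adjusted p = 0.494 with an estimated correlation). The ruxolitinib Schwann call was lost without ruxolitinib mouse 6 (adjusted p = 0.114), with separate day-0 means (0.0858) and with the muscle covariate (0.195). The tofacitinib Schwann call was lost with the muscle covariate (-0.33, adjusted p = 0.755), without tofacitinib mouse 7 (0.0755) or 8 (0.0811) and without the day-0 array of mouse 3 (0.0513), 6 (0.0517), 8 (0.0569) or 9 (0.0503). It was also lost without a filter (0.0558), with a filter at 6 (0.106), with array weights (0.0603), with the mean of probe sets (0.0657), with the 3' minus 5' covariate (0.0882) and without the day-0 arrays of mice 1, 3, 8 and 9 (0.109). Basal keratinocyte markers fell in 10 and 11 of 12 cases, also adjusted over the list alone (adjusted p = 0.000183 and 5.18e-05, and adjusted p = 0.195 and adjusted p = 0.196 with an estimated correlation). Other lists called with both drugs were Wnt (7 and 9 of 15 lower, 1 higher in each, adjusted p = 0.00669 and 0.00244), BMP (5 and 7 of 13 lower, 1 and 2 higher, adjusted p = 0.0156 and 0.0254) and regulatory T cells (4 of 4 lower in each, adjusted p = 0.00263 and 0.00629). Extracellular matrix genes were called higher, although only 3 and 4 of 19 rose and 1 fell in each (adjusted p = 0.0156 and 0.0254). Adjusted over the list alone the counts differed only for BMP, with 7 and 8 lower. Macrophage genes were called with ruxolitinib (6 of 15 higher and 1 lower, also adjusted over the list alone, adjusted p = 0.0230), and immediate early genes with tofacitinib (4 of 19 higher and 1 lower, 4 and 0 adjusted over the list alone in limma, adjusted p = 0.0393). With an estimated correlation none of these held (adjusted p from 0.173 to 0.576), and the basal keratinocyte covariate ended each but the macrophage call. Matrix and immediate early genes were higher with vehicle too. The matrix mean was 7.878 at day 0, 8.509 with vehicle, 8.58 with ruxolitinib and 8.602 with tofacitinib. The immediate early mean was 8.915, 9.851, 9.736 and 9.81 in the same order. Without ruxolitinib mouse 4 the Wnt (adjusted p = 0.0697), BMP (0.0699) and macrophage calls (0.0790) were lost. The macrophage call was also lost without a filter (0.0909), with a filter at 6 (0.105) and with only the groups compared (0.0627). For tofacitinib the BMP call was lost with the mouse as a fixed block (0.0560). The matrix call was lost in that fit (0.0573), without a filter (0.0521), with separate day-0 means (0.125), with the muscle covariate (0.0800), and without tofacitinib mouse 7 (0.128) or the day-0 array of mouse 6 (0.0513). The immediate early call was lost with the mouse as a fixed block (0.335), with separate day-0 means (0.386), without a filter (0.0732), with the mean of probe sets (0.0593), with the 3' minus 5' covariate (0.0518) and without the day-0 arrays of mice 1, 3, 8 and 9 (0.0625). It was also lost without tofacitinib mouse 7 (0.105) or 8 (0.0774) or the day-0 array of mouse 4 (0.0534), 5 (0.0610) or 6 (0.0703). In every fit with an array left out, 11 of the 18 ruxolitinib and 13 of the 19 tofacitinib list calls against day 0 held. For ruxolitinib the count was 1324 with the mouse as a fixed block, 42 with the basal keratinocyte covariate, 2315 without ruxolitinib mouse 4, 1999 without ruxolitinib mouse 6 and 1877 at an absolute log2 change of at least 1. For tofacitinib it was 2521 with the muscle covariate, where Cish no longer passed (adjusted p = 0.0894), 5 with the basal keratinocyte covariate, 3969 without tofacitinib mouse 9 and 2380 at an absolute log2 change of at least 1.

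The inhibitors were then compared with vehicle at day 5, which asks what the drugs changed beyond the vehicle and the biopsies. Averaged over both drugs, 113 genes differed from vehicle, 101 higher and 12 lower. Higher here means above vehicle and not above day 0. The inhibitor mean of 45 of the 101 genes lay below every day-0 array, that of 31 within the day-0 range and that of 25 above it. Vehicle lay below day 0 past the threshold for 80 of the 101 and above it for 10 of the 12. The same vehicle arrays chose these genes, so these counts describe them and are no separate test. The pigment genes stood out. Tyrp1 was 9.62-fold higher (3.27 ± 0.43, 5 against 2 arrays, adjusted p = 0.00341), Pmel 8.62-fold (3.11 ± 0.35, adjusted p = 0.00184), Dct, another melanin synthesis enzyme, 6.75-fold (2.76 ± 0.54, adjusted p = 0.0335) and Tyr at least 3.42-fold. The lowest of the 3 Tyrp1 probe sets stood at 1.70. Of 8 melanocyte genes 5 were higher and 3 did not pass (6 higher adjusted over the list alone, adjusted p = 8.55e-09, and adjusted p = 0.0828 with an estimated correlation). Tyrp1 averaged 4.35 ± 0.54 (SD, n = 9) at day 0, 4.60 ± 0.72 (n = 2) with vehicle, 8.13 ± 0.24 (n = 2) with ruxolitinib and 7.78 ± 0.57 (n = 3) with tofacitinib.

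Some hair follicle genes were higher with the inhibitors. Shh, the hedgehog ligand of growing follicles (Entrez gene 20423), was higher by 3.23 ± 0.66 (adjusted p = 0.0412). Its vehicle arrays (2.73 and 2.27) lay near the highest control value of 2.43, so no fold is given. Hoxc13, a transcription factor of the hair shaft (Entrez gene 15422), was 3.02-fold higher (1.59 ± 0.24, adjusted p = 0.00823) and Krt25, an inner root sheath keratin, 3.59-fold (1.84 ± 0.41, adjusted p = 0.0488). Of 10 hedgehog pathway genes 1 was higher (3 adjusted over the list alone, list adjusted p = 0.00108, and adjusted p = 0.115 with an estimated correlation). Its mediator Gli2 (1.12 ± 0.33, adjusted p = 0.128) and receptor Ptch1 (0.47 ± 0.14, adjusted p = 0.130) did not pass over all genes. Of 5 hair shaft and matrix genes 1 was higher (3 adjusted over the list alone, adjusted p = 0.000160, and adjusted p = 0.0668 with an estimated correlation). Only these 5 of the 26 members of that list were tested, so its result covers a small part of the list. None of 15 Wnt genes passed over all genes in limma, with Rnf43 closest at 1.20 ± 0.29 (adjusted p = 0.0644), and 3 were higher adjusted over the list alone (list adjusted p = 0.00533, adjusted p = 0.0896 with an estimated correlation and 0.0522 with the mouse as a fixed block). The Wnt call was also lost without ruxolitinib mouse 6 (adjusted p = 0.0685) and with separate day-0 means (0.0593), and the hair shaft call without a filter (0.0901). Other follicle lists did not pass. These were the inner root sheath (1 of 6 higher, also adjusted over the list alone, adjusted p = 0.186), bulge stem cells (0 of 20 in limma, 1 lower adjusted over the list alone, adjusted p = 0.397) and the dermal papilla (0 of 14 in limma, 1 higher adjusted over the list alone, adjusted p = 0.497).

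Epidermal and proliferation genes, lower in vehicle than at day 0, were higher with the inhibitors than with vehicle. Tgm3, a transglutaminase of the cornified envelope and hair, was 7.31-fold higher (2.87 ± 0.45, adjusted p = 0.00823, with 1.48 in its other probe set), Klk13, a kallikrein protease, 8.17-fold, Casp14, a caspase of cornification, 3.53-fold, Asprv1, a protease of the granular layer, 2.11-fold and Krt1 1.60-fold. Of 21 epidermal differentiation genes 5 were higher (16 adjusted over the list alone, adjusted p = 3.68e-16, and adjusted p = 0.0668 with an estimated correlation). Of 32 cell cycle genes 3 were higher, namely Bub1b (1.96 ± 0.38), Mki67 (1.46 ± 0.29) and the mitotic kinesin Kif11 (1.76 ± 0.39), and 23 were adjusted over the list alone (list adjusted p = 4.79e-16, and adjusted p = 0.141 with an estimated correlation). Muscle markers did not pass as a list for both drugs averaged, with a median of -0.17 (adjusted p = 0.0733) and 0 of 20 genes past the threshold, also adjusted over the list alone, in limma. For ruxolitinib alone the muscle list was called lower than vehicle (median -0.22, list adjusted p = 0.0348).

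Among the 12 genes lower with the inhibitors, Mmp10 was 11.4-fold lower (-3.51 ± 0.54, adjusted p = 0.00823), the axonal adhesion gene Cntnap2 4.05-fold (-2.02 ± 0.31) and Ifi202b, an interferon-inducible gene of the p200 family, 7.73-fold (-2.95 ± 0.66, adjusted p = 0.0495). The JAK-STAT feedback and target list did not pass (0 of 14 genes in limma, 2 lower adjusted over the list alone, median -0.22, adjusted p = 0.120), and passed only with the muscle covariate (-0.12, adjusted p = 0.0472). Its 2 members with the smallest p were Socs3 (-1.40 ± 0.32, adjusted p = 0.0550, lower in 5 of 5 inhibitor arrays than in either vehicle array) and Bcl3, a STAT3-responsive IkB family gene (-1.60 ± 0.42, adjusted p = 0.0869). Interferon-stimulated genes did not pass as a list (0 of 26 genes in limma, also adjusted over the list alone, median -0.15, adjusted p = 0.197). With the mouse as a fixed block this median was 0.30 (adjusted p = 0.0215) and with separate day-0 means 0.13 (0.584), above vehicle rather than below it. It passed below vehicle without vehicle mouse 2 (-0.34, adjusted p = 0.0152) and with only the groups compared (-0.20, adjusted p = 0.0257). Usp18 (-1.03 ± 0.39, adjusted p = 0.245) and Rtp4, an interferon-induced chaperone gene (-1.18 ± 0.50), did not pass. The kinases targeted by the drugs did not pass either, with Jak1 at -0.22 ± 0.20, Jak2 at -0.01 ± 0.12 and Tyk2 at 0.32 ± 0.23, nor did Cish (0.03 ± 0.49) and Socs2 (-0.57 ± 0.48). Probe sets of Jak1 differed in sign, and Jak3 and Socs1 were not tested because their values lay below the filter. Langerhans and dendritic cell markers were lower as a list (median -0.43, adjusted p = 0.0170, and adjusted p = 0.567 with an estimated correlation, 0 of 8 genes past the threshold in limma, also adjusted over the list alone), with Cd83 at -0.95 ± 0.50. That call was lost without vehicle mouse 3 (adjusted p = 0.132), ruxolitinib mouse 4 (0.0955) or tofacitinib mouse 8 (0.0605), and without a filter (0.223). Sebaceous gland and lipid synthesis genes were higher as a list (median 0.25, adjusted p = 0.000958, and adjusted p = 0.498 with an estimated correlation, 0 of 16 genes past the threshold in limma, also adjusted over the list alone).

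**Figure D2:**
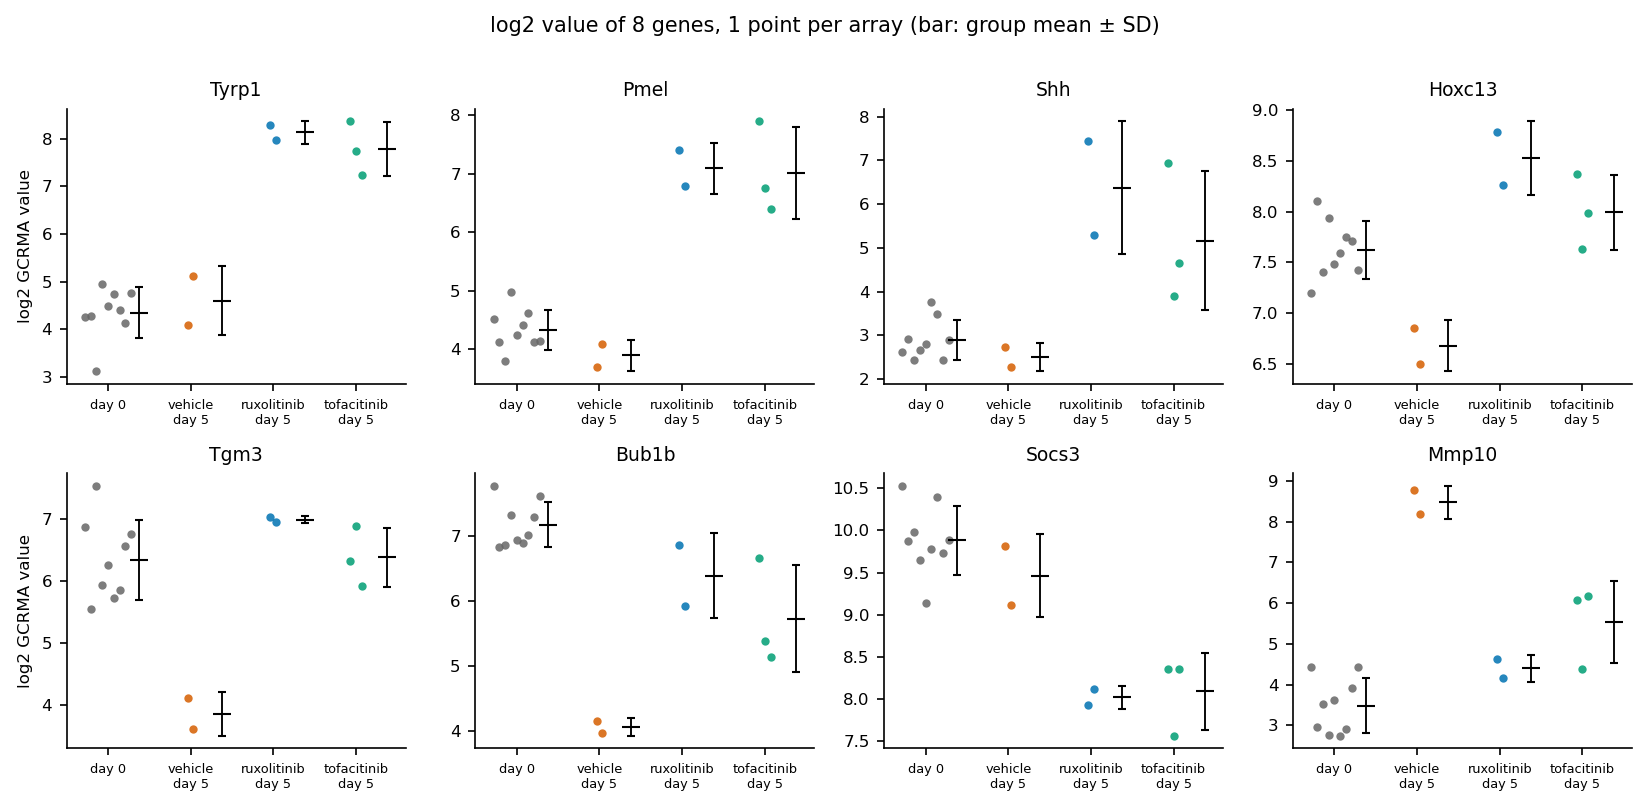
log2 GCRMA value (vertical axes, each with its own range) of 8 genes in the 4 groups, with 1 point per array and bars for the group mean ± SD. Every inhibitor array lay above both vehicle arrays for Tyrp1, Pmel, Shh, Hoxc13, Tgm3 and Bub1b and below both for Socs3 and Mmp10. Such separation held for 15.95% of all tested genes, where chance gives 9.52%. Tyrp1, Pmel, Shh, Tgm3 and Mmp10 were named by a rule that required it, so it is no separate support.

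These calls against vehicle depended on single arrays. Of the 18 named genes that passed, none passed in every fit with an array left out. Without vehicle mouse 2 no gene passed in limma (941 at an unadjusted p under 0.05), without vehicle mouse 3 there were 22, and without ruxolitinib mouse 4, tofacitinib mouse 7 or tofacitinib mouse 8 there were 50, 48 and 50. Without tofacitinib mouse 9 there were 374. With the mouse as a fixed block none passed (1039 at an unadjusted p under 0.05, with Tyrp1 at 2.42), and with only the groups compared none passed (1532 at an unadjusted p under 0.05). With separate day-0 means 23 did, without the filter 71, with the basal keratinocyte covariate 35 and with a covariate of RNA quality, the 3' minus 5' signal of control genes and also chosen after seeing the data, 44. At an adjusted p of 0.1 there were 287. Over all alternatives and left-out arrays the adjusted p of Shh ran from 0.0208 to 0.518, that of Tgm3 from 0.00251 to 0.428 and that of Mmp10 from 0.00251 to 0.428.

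Taken alone, ruxolitinib differed from vehicle in 63 genes, 49 higher and 14 lower. Rel, a subunit of the transcription factor NF-kB (Entrez gene 19696), was 17.9-fold higher (4.17 ± 0.33, 2 against 2 arrays, adjusted p = 2.77e-05), Tyrp1 10.7-fold, Ces2f, a carboxylesterase gene, 10.8-fold, Tgm3 9.18-fold, Pmel 8.73-fold, Hoxc13 3.61-fold and Bub1b 4.93-fold. Other probe sets gave a log2 difference of only 0.81 for Ces2f, 1.65 for Tgm3 and, at the lowest, 1.70 for Tyrp1. Rel had a single kept probe set, so its value could not be checked in this way. It is among 58 probe sets lower in tofacitinib than in ruxolitinib arrays. Other probe sets of those genes differed by a median of only -0.11 between the drugs. Shh was higher by 3.82 ± 0.79, again against vehicle values near background. Krt25 did not pass (2.29 ± 0.49, adjusted p = 0.0521). Ifi202b was 18.6-fold lower (-4.21 ± 0.79, adjusted p = 0.0310), Mmp10 16.4-fold (-4.04 ± 0.65, adjusted p = 0.0180), Sh2d5, an SH2 domain adaptor gene, 5.12-fold and Cntnap2 4.80-fold. Socs3 (-1.42 ± 0.38, adjusted p = 0.0919) and Bcl3 (-1.89 ± 0.50, adjusted p = 0.0893) did not pass. Among the lists, melanocytes (3 of 8 higher, 6 adjusted over the list alone, adjusted p = 2.59e-07), epidermal differentiation (1 of 21, 14 adjusted over the list alone, adjusted p = 3.38e-11), cell cycle (1 of 32, 23 adjusted over the list alone, adjusted p = 1.57e-15), the hedgehog pathway (1 of 10, 4 adjusted over the list alone, adjusted p = 0.000688) and the hair shaft (1 of 5, 3 adjusted over the list alone, adjusted p = 0.000807) were higher. With an estimated correlation none of these held, with adjusted p = 0.106 for each but the cell cycle, where adjusted p = 0.147. Skeletal muscle was lower as a list (median -0.22, adjusted p = 0.0348, and adjusted p = 0.897 with an estimated correlation). This call was lost without ruxolitinib mouse 4 (adjusted p = 0.117), without vehicle mouse 3 (0.235), with the 3' minus 5' covariate (0.178) and without the mouse term (0.0625), and the hair shaft call without a filter (0.189). Langerhans and dendritic cell markers were also lower as a list (0 of 8 in limma, also adjusted over the list alone, median -0.56, adjusted p = 0.0140, and adjusted p = 0.542 with an estimated correlation). This call was lost with the mouse as a fixed block (adjusted p = 0.368), with separate day-0 means (0.420), without a filter (0.211), without vehicle mouse 3 (0.0527) and without ruxolitinib mouse 4 (0.201). Sebaceous gland and lipid synthesis genes (0 of 16 in limma, also adjusted over the list alone, median 0.40, adjusted p = 0.000244, and adjusted p = 0.414 with an estimated correlation) were higher. So were Wnt genes (0 of 15 in limma, 1 adjusted over the list alone, median 0.65, adjusted p = 0.00988, and adjusted p = 0.106 with an estimated correlation). The Wnt call was lost with the mouse as a fixed block (adjusted p = 0.0927), with separate day-0 means (0.110), with the basal keratinocyte covariate (0.0562) and without ruxolitinib mouse 6 (0.267). Without ruxolitinib mouse 4 the cell cycle median was 0.84 and the hair shaft median 0.79. The gene count fell to 16 or fewer without any of the 4 arrays (1 without vehicle mouse 2, 16 without vehicle mouse 3, 4 without ruxolitinib mouse 4 and 15 without ruxolitinib mouse 6). It was 0 in limma with the mouse as a fixed block (1893 at an unadjusted p under 0.05), 3 with only the groups compared, 20 with the basal keratinocyte covariate, 36 with the 3' minus 5' covariate, 104 with the muscle covariate, 247 with separate day-0 means, 191 with array weights, 110 with the mean of probe sets, 199 with each probe set on its own and 300 at an adjusted p of 0.1.

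Tofacitinib differed from vehicle in 20 genes, all higher (0 lower in limma, 250 lower at an unadjusted p under 0.05). Tyrp1 was 8.64-fold higher (3.11 ± 0.46, 3 against 2 arrays, adjusted p = 0.0146), Pmel 8.51-fold (3.09 ± 0.37, adjusted p = 0.00503) and Tyr at least 3.13-fold. Car6, a secreted carbonic anhydrase gene with a vehicle array below 2.43, was higher by 2.74 ± 0.39. Others were Gprin2 (4.99-fold), the epidermal lipase gene Lipk (4.70-fold), Lrrc15 (4.56-fold), the arginase gene Arg2 (3.92-fold) and the sphingosine kinase gene Sphk1 (3.54-fold, with a log2 difference of 0.36 in its other probe set). Tgm3 (2.54 ± 0.49, adjusted p = 0.0507), Hoxc13 (1.33 ± 0.26, adjusted p = 0.0623), Shh (2.64 ± 0.72, adjusted p = 0.171), Bub1b (1.62 ± 0.41, adjusted p = 0.146), Mmp10 (-2.99 ± 0.59, adjusted p = 0.0623), Cntnap2 (-1.77 ± 0.33, adjusted p = 0.0507) and Socs3 (-1.38 ± 0.35, adjusted p = 0.146) did not pass. The melanocyte (3 of 8 genes, 6 adjusted over the list alone), epidermal differentiation (0 of 21 in limma, 16 adjusted over the list alone) and hair shaft lists (0 of 5 in limma, 3 adjusted over the list alone) were higher, with adjusted p of 3.64e-10, 8.77e-21 and 5.50e-05. These 3 calls held with an estimated correlation (adjusted p = 0.0440, 0.0284 and 0.0406), and with the Wnt list in vehicle against day 0 they were the only list calls that did. The hair shaft call rests on 5 of the 26 members of that list. Cell cycle genes were higher as a list (0 of 32 in limma, 3 adjusted over the list alone, median 0.92, adjusted p = 1.20e-12, and adjusted p = 0.287 with an estimated correlation). The cell cycle list means were 8.35, 7.58 and 6.83 in tofacitinib mice 7, 8 and 9, against 6.65 and 6.68 with vehicle. Without mouse 7, the array with conflicting labels, the median was 0.46 for the cell cycle list and 0.56 for the hair shaft list, and both calls held. Hedgehog (0 of 10 in limma, 1 adjusted over the list alone, median 0.29, adjusted p = 0.0136), Wnt (0 of 15 in limma, also adjusted over the list alone, median 0.40, adjusted p = 0.0136) and sebaceous gland and lipid synthesis genes (0 of 16 in limma, also adjusted over the list alone, median 0.19, adjusted p = 0.0303) were higher as lists. With an estimated correlation these did not hold (adjusted p = 0.287, adjusted p = 0.131 and adjusted p = 0.726). The Wnt call was lost with the mouse as a fixed block (adjusted p = 0.0642), with separate day-0 means (0.0627), with a filter at 6 (0.0589) and with the basal keratinocyte covariate (0.0541). The lipid call was lost without vehicle mouse 3 (adjusted p = 0.273) or tofacitinib mouse 8 (0.221). Markers of other cell types moved as well. Schwann cell genes were lower as a list (0 of 7 in limma, also adjusted over the list alone, median -0.69, adjusted p = 0.0170, and adjusted p = 0.697 with an estimated correlation). This call was lost without vehicle mouse 3 (adjusted p = 0.197) or tofacitinib mouse 9 (0.0859), with a filter at 6 (0.0773) and with the basal keratinocyte covariate (0.186). Mast cell genes were higher as a list (median 0.74, adjusted p = 0.0351, and adjusted p = 0.697 with an estimated correlation), a call lost in 8 other fits. Interferon-stimulated genes were lower (0 of 26 in limma, also adjusted over the list alone, median -0.29, adjusted p = 0.0351, and adjusted p = 0.726 with an estimated correlation), with Usp18 at -1.06 ± 0.43 and Rtp4 at -1.29 ± 0.54. The JAK-STAT feedback and target list did not pass (0 of 14 genes in limma, 1 lower adjusted over the list alone, median -0.11, adjusted p = 0.192), but it did with the mouse as a fixed block (-0.36, adjusted p = 0.00343), with separate day-0 means (-0.44, 0.0211) and without tofacitinib mouse 7 (-0.18, 0.0482). The interferon median was 0.23 with the mouse as a fixed block (adjusted p = 0.194), and its call was lost with separate day-0 means (adjusted p = 0.687), with a filter at 6 (0.103), with the muscle covariate (0.0555), and without vehicle mouse 3 (adjusted p = 0.305), tofacitinib mouse 8 (0.111) or tofacitinib mouse 9 (0.0646). The gene count was 0 in limma without vehicle mouse 2 (618 at an unadjusted p under 0.05), with the mouse as a fixed block (430), with separate day-0 means (705) and with only the groups compared (848). It was 13 without vehicle mouse 3, 6 without tofacitinib mouse 7, 7 without tofacitinib mouse 8, 126 without tofacitinib mouse 9, 63 with the muscle covariate, 35 with array weights, 32 with a trended robust fit, 12 with the mean of probe sets, 12 with each probe set on its own, 11 without the filter, 11 with a filter at 6 and 49 at an adjusted p of 0.1.

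**Figure D3:**
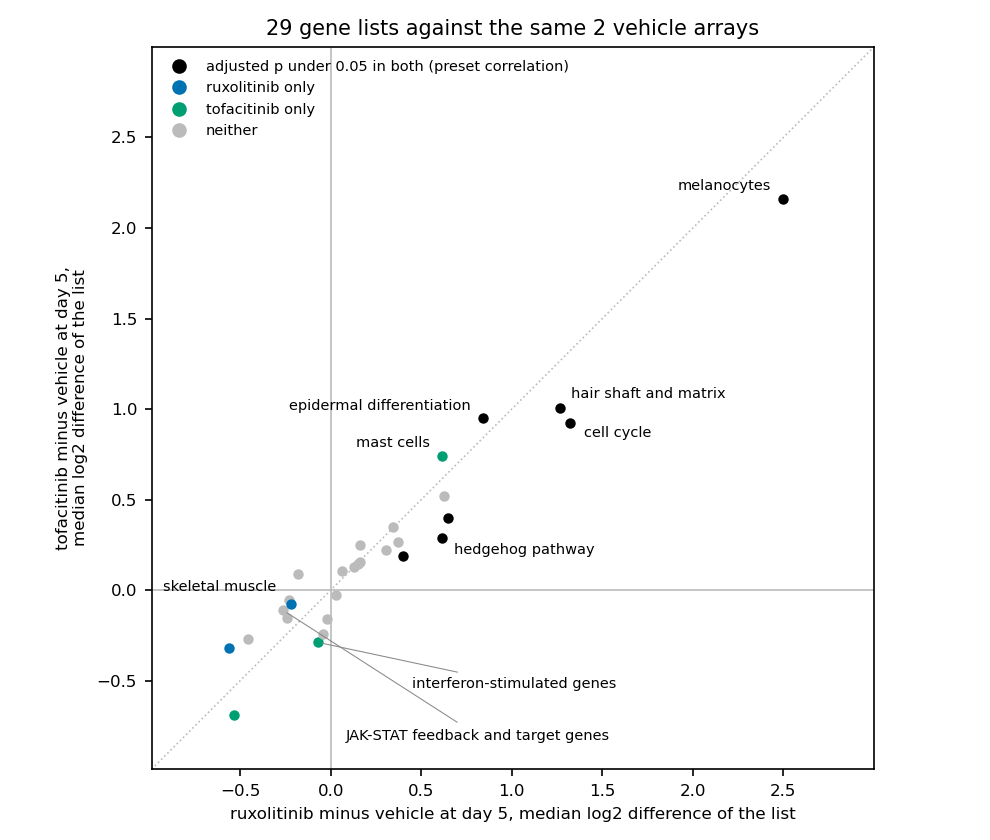
Median log2 difference of 29 gene lists, ruxolitinib minus vehicle (horizontal) against tofacitinib minus vehicle (vertical), 1 point per list, coloured by whether the list passed with the preset correlation. The melanocyte list lay at 2.50 and 2.16 and the cell cycle list at 1.32 and 0.92, and both axes share the same 2 vehicle arrays.

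The inhibitors were compared with each other after the same 4 days of daily treatment, although their doses are not given in the sources used here and may differ. Tofacitinib skin was lower than ruxolitinib skin in 3 genes and higher in none (in limma, 355 higher at an unadjusted p under 0.05). Rel was 12.9-fold lower (-3.69 ± 0.30, 95% interval -4.34 to -3.06, 3 against 2 arrays, adjusted p = 4.11e-05), with 8.45 ± 0.11 (SD, n = 2) in ruxolitinib arrays, 4.80 ± 0.57 (n = 3) in tofacitinib arrays and 4.29 ± 0.14 (n = 2) in vehicle arrays. Cdk13, a transcriptional cyclin-dependent kinase, was 5.85-fold lower (-2.55 ± 0.36, adjusted p = 0.0212) and Prmt6, an arginine methyltransferase, 2.44-fold (-1.29 ± 0.19, adjusted p = 0.0275). With the mouse as a fixed block Rel stood at -4.10 (adjusted p = 0.364), Cdk13 at -3.06 and Prmt6 at -1.33 (0.386 each), and none passed. The other probe sets stood at 0.02 for Cdk13 and -0.19 for Prmt6, and Rel had no other kept probe set. Nsd3, a histone methyltransferase (-1.22 ± 0.21, adjusted p = 0.0988), Tmprss11a (2.64 ± 0.57, adjusted p = 0.254) and Rpusd4, a mitochondrial pseudouridine synthase (1.13 ± 0.23, adjusted p = 0.237), did not pass, and probe sets of Nsd3 differed in sign.

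For Socs3 and named genes that had passed against vehicle with both drugs averaged, the difference between the drugs was not resolved. The 95% interval of tofacitinib minus ruxolitinib was -1.30 to 0.68 for Tyrp1, -2.71 to 0.35 for Shh, -1.70 to 0.38 for Tgm3, -1.08 to 0.05 for Hoxc13, -1.55 to 0.19 for Bub1b, -0.21 to 2.31 for Mmp10 and -0.70 to 0.79 for Socs3, and none of these passed (adjusted p from 0.894 to 0.991). Cell cycle genes were lower as a list with tofacitinib than with ruxolitinib (0 of 32 genes in limma, also adjusted over the list alone, median -0.42, adjusted p = 3.77e-05, and adjusted p = 0.988 with an estimated correlation), as were sebaceous gland and lipid synthesis genes (0 of 16 in limma, also adjusted over the list alone, median -0.17, adjusted p = 0.00957, and adjusted p = 0.988 with an estimated correlation). The cell cycle call was lost without ruxolitinib mouse 4 (median -0.07, adjusted p = 0.741) or tofacitinib mouse 9 (-0.03, adjusted p = 0.329). The lipid call was lost without ruxolitinib mouse 4 (adjusted p = 0.142), without tofacitinib mouse 7 (0.170), with array weights (0.0505), with separate day-0 means (0.611) and with the mouse as a fixed block (0.319). The gene count was 0 in limma with the mouse as a fixed block (1492 at an unadjusted p under 0.05) or only the groups compared (369), 1 without ruxolitinib mouse 4 or tofacitinib mouse 9, 9 without tofacitinib mouse 7, 5 with separate day-0 means, with the mean of probe sets or with the basal keratinocyte covariate, and 56 genes with each probe set on its own.

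Similarity of the responses was described across genes, which are not independent replicates. Mean within-mouse changes from day 0 to day 5 correlated across 12087 genes with Pearson r = 0.777 (Spearman 0.720) between ruxolitinib and tofacitinib, 0.709 (0.661) between ruxolitinib and vehicle, and 0.915 (0.912) between tofacitinib and vehicle. Each arm used its own day-0 arrays. On the leading principal component these lay at -20.9 and -61.1 (vehicle), -26.2 and -18.7 (ruxolitinib) and -34.9, -67.3 and -55.1 (tofacitinib). Differences between the correlations may therefore come in part from the day-0 arrays, and they do not rank the drugs by likeness to vehicle. Without ruxolitinib mouse 4 the correlation of the drugs was 0.664. Differences from vehicle correlated with r = 0.791 between the drugs and a covariance of 0.176. Simulated groups without any effect, sharing a simulated vehicle group, gave means of 0.546 and 0.0662. Each gene was drawn independently there, while genes on the real arrays vary together, and only the means were kept. The simulation therefore cannot decide whether the drugs shared an effect. Of the 63 genes that differed from vehicle with ruxolitinib, 61 had the same sign with tofacitinib and 14 passed there, all higher. Independent lists of the 49 and 20 higher genes would share 0.0811. Both comparisons used the same 2 vehicle arrays, which were too few to give each comparison 2 of its own, so part of this overlap may come from sharing them.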

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

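The keratinocyte-share tests and the muscle, fat and hair follicle share tests of the melanocyte genes were chosen only after the result was seen. The RNA integrity test was written down before, but it uses the 3' minus 5' covariate, which like the basal keratinocyte covariate was added after seeing the data. The other muscle-share tests and the test of other groupings of the arrays were written down before. No biological explanation beyond the labelled treatments was tested.

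Melanocyte genes were higher as a list with the inhibitors than with vehicle, with the preset correlation. Over all genes 5 of 8 members passed, and the list call did not hold with an estimated correlation (adjusted p = 0.0828). A different muscle share of the biopsy could shift a cell type, but with the muscle covariate the list median stayed at 2.32 (quartiles 1.63 and 2.94), against 2.33 without it. A larger fat or hair follicle share would raise the genes of those tissues as well, but the lower quartile of the melanocyte list (1.36) lay 0.971 above the upper quartile of the adipocyte list (0.39) and 0.534 above that of 45 hair follicle genes (0.82). Loss of RNA integrity alone was not enough, since with the 3' minus 5' covariate the list median stayed at 2.30 (quartiles 1.51 and 2.79), against 2.33 without it. The 5 tested hair shaft genes alone, of 26 on their list, overlapped with the melanocyte genes (quartiles 0.48 and 1.42). More growing follicles therefore stay open beside an effect of treatment and a chance difference of the animals or sites. Against day 0, however, the upper quartiles of the hair shaft list (0.78 for ruxolitinib and 0.38 for tofacitinib) lay below the lower quartiles of the melanocyte list (1.61 and 1.66).

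Epidermal differentiation and cell cycle genes were lower as lists in vehicle arrays than in inhibitor arrays, with the preset correlation. Over all genes 5 of 21 and 3 of 32 members passed. Neither list call held with an estimated correlation (adjusted p = 0.0668 and 0.141). A smaller keratinocyte share in the vehicle arrays might lower all keratinocyte genes alike. The lower quartile of the differentiation list (0.61) lay 0.352 above the upper quartile of the basal list (0.26), which that explanation alone does not allow. A larger muscle share in the vehicle arrays was set against the cell cycle genes, whose median with the muscle covariate was 1.01 (quartiles 0.63 and 1.32), against 1.15 without it. Both tests leave a treatment effect open, and neither shows it.

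A large share of the genes differed between day 0 and day 5. With the muscle covariate 37.2% of the tofacitinib calls against day 0 were left (2252 of 6055). The muscle list mean also separated the days completely, with at most 13.01 at day 0 and at least 13.08 at day 5. The covariate thus takes up part of the day difference by construction. A part of the calls may reflect biopsy depth, but the test could not tell whether or how much. A smaller keratinocyte share at day 5 might explain why 11 of 12 basal markers fell in vehicle skin and why 5 genes and not 6178 changed with the basal covariate, which separates the days, and it stays open for those genes, but not for the activated keratinocyte genes, whose lower quartile (-0.03) lay 0.621 above the upper quartile of the basal list (-0.65). Among 100 of the 220 possible splits of the 12 arrays, only 1, the real grouping, gave as many genes as 6055, the highest other gave 2320 and of the 8 that part all 3 pairs all but the real one gave at most 2. Time, the first biopsy and daily handling changed together between the days and were not separable.

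In 112 list means and genes, 6 had a day-0 array far from the other 8, where chance gives about 5%. The gap over the range was 0.613 for Actc1 (mouse 8, highest), 0.544 for C1qa (mouse 1, lowest), 0.533 for Fosl1 (mouse 7, highest), 0.499 for Jak2 (mouse 1, highest), 0.521 for Krt25 (mouse 9, highest) and 0.551 for Tyrp1 (mouse 3, lowest). A direct test found a difference between the inhibitors for Rel (-3.69), Cdk13 (-2.55) and Prmt6 (-1.29), none of which passed with the mouse as a fixed block. Other probe sets stood at 0.02 for Cdk13 and -0.19 for Prmt6, and Rel had no other kept probe set. The list test on moderated t values, with the preset correlation, called the cell cycle list (median -0.42) and the sebaceous gland and lipid synthesis list (median -0.17), and neither held with an estimated correlation (adjusted p = 0.988 each). Without ruxolitinib mouse 4 or tofacitinib mouse 9 the cell cycle median was -0.07 or -0.03 and the call was lost, and the lipid call was lost in 5 fits given in the report. Among 3564 probe sets without exactly 1 gene symbol, which the comparisons did not use, 3 passed for both inhibitors against vehicle, 2 higher and 1 lower. For ruxolitinib against vehicle 24 passed, 16 higher and 8 lower, for tofacitinib against vehicle 0 in limma, and for tofacitinib against ruxolitinib 14, all lower.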

How the results depend on the processing

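Without the mouse term and with quantile normalization every count of changed genes stayed within 1.5 times its value, and no other normalization of the deposited values was tried. Apart from left-out arrays, the 160 named gene results kept direction and side of the threshold in 1861 of 2145 fits, and the 90 list results in 1080 of 1306. With an array left out this held for 1208 of 1359 and 736 of 797. Lost calls numbered 247 for genes and 193 for lists (134 and 59 with an array left out), and gained calls 22 and 9 (8 and 2). The estimated correlation ended 78 of the list calls. In every fit with an array left out, 39 of 39 named calls held for vehicle, 20 of 20 for ruxolitinib and 21 of 21 for tofacitinib against day 0, but 1 of 13, 0 of 9 and 0 of 18 against vehicle (ruxolitinib, tofacitinib, both) and 1 of 3 between the drugs. Where an array left out leaves a single array in its group, that array was assumed to vary like the others. A filter at 6 gave no value for 17 named results, fits per probe set gave no single value for a gene or list, and a list used as covariate has no value under its own covariate. Differences from vehicle rest on 2 arrays, and values near the background of 2.43 bound the folds. Unless stated, the cause was not tested.

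Below, counts of changed genes are ordered as vehicle, ruxolitinib and tofacitinib against day 0, then ruxolitinib, tofacitinib and both against vehicle, then tofacitinib against ruxolitinib, with the reported 6178, 4104, 6055, 63, 20, 113 and 3. Each sentence gives only the counts that moved by over 1.5 times. The mouse as a fixed block, the paired fit, which has fewer arrays and fewer degrees of freedom, gave 3701 and 1324 for the vehicle and ruxolitinib comparisons with day 0, and 0 in limma for all 4 others at day 5 (1893, 430, 1039 and 1492 at an unadjusted p under 0.05). In this paired fit the interferon list turned upward against vehicle for ruxolitinib (0.40), tofacitinib (0.23) and both (0.30), Jak2 stood at 0.0742 and Cish at -0.30 for both, and between the drugs Tyrp1 stood at 0.0667 and Socs3 at -0.22. It ended 46 named gene calls and 15 list calls and reversed no called gene. Separate day-0 means gave 247 (ruxolitinib), 0 in limma (tofacitinib, 705 unadjusted) and 23 (both) against vehicle and 5 between the drugs, with the interferon list at 0.25 (ruxolitinib) and 0.13 (both), Jak2 at 0.15 and Cish at -0.16 for both, and Socs3 at -0.40 between the drugs. Only the groups compared, with fewer arrays for the spread, gave 3, 0 and 0 in limma against vehicle (2198, 848 and 1532 unadjusted) and 0 between the drugs (369 unadjusted).

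Array weights gave 191 and 35 for ruxolitinib and tofacitinib against vehicle, with Socs3 at -0.19 between the drugs, and trended robust moderation 32 for tofacitinib against vehicle. The mean of probe sets gave 110 and 12 against vehicle and 5 between the drugs, and each probe set on its own 199 and 12, and 56. No filter gave 11 (tofacitinib) and 71 (both) against vehicle, and a filter at 6 gave 11 for tofacitinib. An adjusted p of 0.1 gave 300, 49 and 287 against vehicle, by construction more, and an absolute log2 change of at least 1 gave 3071, 1877 and 2380 against day 0, by construction fewer. Quantile normalization put Cish at -0.00763 for both inhibitors against vehicle.

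The muscle covariate, which also separates the days, gave 2593 and 2521 for vehicle and tofacitinib against day 0 and 104 and 63 against vehicle. With it adipocytes stood at -1.27 (vehicle) and -0.48 (tofacitinib) and Schwann cells at -0.33 (tofacitinib) against day 0, Socs3 at 0.0403 (vehicle against day 0) and Cish at -0.12 (both against vehicle). The basal keratinocyte covariate, chosen after seeing the data, separates the days and so takes up most of their difference by construction. It gave 5, 42 and 5 against day 0, 20 (ruxolitinib) and 35 (both) against vehicle and 5 between the drugs. With it, against day 0, T and NK cells stood at 0.35 (vehicle) and -0.17 (tofacitinib, by a reversed test), regulatory T cells at -0.34 (vehicle, by a reversed test), adipocytes at -4.20, -2.38 and -2.55, muscle at -0.93, -0.88 and -0.79, Schwann cells at -0.75, -0.61 and -1.62 (vehicle, ruxolitinib and tofacitinib each), Langerhans and dendritic cells at 0.70 and 1.20 (ruxolitinib and tofacitinib) and cell cycle at 0.10 (tofacitinib). Itgb4 stood at 0.21 and Socs3 at 0.91 (vehicle) and Cd83 at 1.11 (tofacitinib), and against vehicle muscle stood at 0.0583 (ruxolitinib) and Cish at -0.13 (both). The 3' minus 5' covariate, also chosen after seeing the data, gave 36 (ruxolitinib) and 44 (both) against vehicle.

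With an array left out, counts ran from 3470 to 6416, 1999 to 4214 and 3969 to 6426 against day 0, 1 to 16, 0 to 126 and 0 to 374 against vehicle (0 in limma without vehicle mouse 2, with 618 and 941 unadjusted) and 1 to 9 between the drugs, and the within-mouse correlation of the drugs from 0.664 to 0.786. Signs turned in part of these fits for Jak2 (-0.0421 to 0.0410) and Cish (-0.144 to 0.357) for both against vehicle and for Socs3 (-0.0840 to 0.312) between the drugs, none of them called.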

Other observations

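The comparison with other probe sets of the same gene was chosen only after the results were seen. The test of every kept probe set was planned, and the cell type values come from the fixed lists.

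Mast cell genes rose from day 0 with both drugs. All 6 tested members passed with each, also adjusted over the list alone (list adjusted p = 0.00191 for ruxolitinib and 0.00170 for tofacitinib, with adjusted p = 0.278 and adjusted p = 0.293 with an estimated correlation). Hdc, the histamine-forming enzyme, rose by 2.10 ± 0.47 and 2.47 ± 0.40, and Cma1, a mast cell chymase, by 2.15 ± 0.39 with tofacitinib. In vehicle skin 2 of the 6 rose (5 adjusted over the list alone, list adjusted p = 0.0568). Against vehicle the list did not pass for both drugs averaged (median 0.68, adjusted p = 0.0811). It passed for tofacitinib (0 of 6 genes in limma, also adjusted over the list alone, median 0.74, adjusted p = 0.0351, and adjusted p = 0.697 with an estimated correlation). That call was lost with the mouse as a fixed block (adjusted p = 0.0642), with separate day-0 means (0.413), without a filter (0.0644), with a filter at 6 (0.270), and without vehicle mouse 2 (0.164) or 3 (0.0703) or tofacitinib mouse 7 (0.285) or 8 (0.0599). Macrophage markers rose in vehicle skin (6 of 15, 5 adjusted over the list alone, list adjusted p = 0.0439, and adjusted p = 0.550 with an estimated correlation), with the complement genes C1qa up by 1.77 ± 0.34 and C1qc by 1.89 ± 0.32. With the mouse as a fixed block this list did not pass (median 0.48, adjusted p = 0.0642), nor without vehicle mouse 2 (0.0624) or the day-0 array of mouse 2 (0.0602), 4 (0.0543), 6 (0.0589) or 9 (0.0511). Langerhans and dendritic cell markers fell in 5 of 8 cases with each drug, also adjusted over the list alone (list adjusted p = 0.00936 and 0.0431, with adjusted p = 0.479 and adjusted p = 0.494 with an estimated correlation). Cd83, a dendritic cell maturation marker, fell by 2.91 ± 0.45 and 1.96 ± 0.39. With the mouse as a fixed block the ruxolitinib list call (adjusted p = 0.0874) and Cd83 with ruxolitinib (-2.52, 0.0604) did not pass. With the muscle covariate Cd83 with tofacitinib (-1.21, 0.0823) and both list calls (0.119 and 0.779) did not pass. The ruxolitinib list call was also lost without ruxolitinib mouse 4 (0.0699), and the tofacitinib list call without tofacitinib mouse 8 (0.136) or 9 (0.0702) or the day-0 array of mouse 1 (0.0547), 3 (0.0513) or 7 (0.0542).

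When every kept probe set was tested on its own, 58 probe sets of 56 genes were lower in tofacitinib than in ruxolitinib arrays, and 0 of 20992 were higher. In 55 of these both ruxolitinib arrays lay above the other 14. Another kept probe set of the same gene existed for 57 of them (98.3%, against 67.7% of all kept probe sets). The median difference was -1.83 for these probe sets and -0.11 for the others of the same genes. Of probe sets higher with ruxolitinib than with vehicle, 178 passed, with medians of 1.70 and 0.47 for the 132 with such another. For both inhibitors against vehicle 126 passed, with medians of 1.5 and 0.79 for 71. Probe sets picked for passing lay above their others there too, but by less. Their others had the same sign in 66 of 71 cases, against 41 of 57 for the probe sets lower in tofacitinib. The set higher with ruxolitinib than with vehicle uses the same ruxolitinib arrays, so it is no independent reference. Picking for passing was not shown to account for the gap between the drugs. Rel had a single kept probe set, so this comparison could not be made for it.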
